A study of Caenorhabditis elegans with 6 samples.

How the data were processed

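Small RNAs were sequenced from whole Caenorhabditis elegans worms at the young mother stage, grown at 20 °C on HT115 bacteria carrying the L4440 vector, per the labels' protocols. RNA was treated with a 5' polyphosphatase before library preparation with the TruSeq small RNA kit, per the labels' protocols. Polyphosphatase turns the 5' triphosphate of secondary small interfering RNAs into a monophosphate that the adapter can be joined to, so these libraries hold secondary small RNAs beside microRNAs (miRNAs) and 21U-RNAs. The 6 libraries form 3 groups of 2: a single mutant of hrde-1 (allele tm1200), an outcrossed strain that lacks meg-3 (allele ax3055) and meg-4 (allele ax3052), and the triple mutant that carries all 3 alleles.

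Per the submitters' processing notes, cutadapt, Bowtie2, HTSeq and DESeq2 were used with the genome build ce10. The versions, roles and settings of these tools, including strand and the handling of reads with several positions, were not given in the sources used here. Loci that overlap another gene, that have an antisense partner or that belong to families of near-identical copies are therefore uncertain as to which gene their reads came from. The authors deposited 3 tables of 42402 loci, each setting 1 strain against another. Per the file headers the values of each library are fpm. In the deposited tables of hrde-1 over N2, the wild type, and of the triple mutant over meg-3 meg-4, the values are a scaled signal whose library columns differ in their sums. In the deposited table of the triple mutant over N2 the values are RPM, the reads of a locus scaled to 1 common total, and every library column has the same sum. Each table also holds a log2 fold change and an adjusted p-value, both made by the authors and named in the file headers, and DESeq2 is named in the submitters' processing notes. The N2 libraries are not in the sample list. Their 4 per-library columns were not used here, nor were 6 mean columns, and comparisons with N2 come from the authors' deposited tables alone, without an error or a number of replicates. Statistics other than the fold change and the adjusted p are not among the deposited columns used here, so gene lists were compared in those tables with 10000 random lists matched on mean level in 20 bins, in place of a set test on the authors' statistic, and no adjustment over the list alone was made there.

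Every value of a library was a whole multiple of that library's smallest value above 0, within a tolerance of 0.001 read, in 100% of its loci above 0. The numbers of reads behind the values were recovered on this basis, with the smallest value taken as 1 read. The recovered reads of the triple mutant libraries were equal at all loci in the 2 tables that hold them. As a check, DESeq2 was run on the recovered reads of the triple mutant and meg-3 meg-4. Its log2 fold changes differed from those in the authors' deposited table by at most 3.6e-05 at the 11871 loci to which the authors gave an adjusted p, and by at most 1.4e-04 at all 28664 loci with both fold changes, and it called 516 loci, among them all 514 of the authors' calls. The recovered reads per library ranged from 2384147 to 6780320. A locus with 0 reads may hold up to 3 reads per library by counting error alone. Reads carry no molecular identifiers, so limits of this kind cover counting error only. The locus with the most reads, mir-82, took between 2.51% and 5.69% of a library.

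Loci were matched by sequence name to a reference annotation from another genome build than ce10, and no coordinates are given for this reason. The reference gave the class of 41759 loci, and 643 stayed unmatched. Symbols are those of the deposited tables, with a later name from the reference where it differs. Gene groups were compared with 24 lists, of which those for HRDE-1 targets and ERGO-1 targets were written from memory. In the list of ERGO-1 targets 1 locus is a miRNA in the reference. The list meant for snRNA and snoRNA was built from name patterns, held 30 snRNA loci and 10 protein-coding genes and no snoRNA, and its calls do not stand for these classes. snRNA and snoRNA loci were therefore also counted by annotation class, a choice made after the data were seen. The lists, the tests, the rule for named genes and the first set of alternatives were chosen before the data were examined.

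The triple mutant was compared with meg-3 meg-4 within the 1 deposited table that holds both. The plan had foreseen edgeR for counts and limma for normalized values, and the values were normalized. limma with an intensity trend was fitted to log2(value + 1) for loci with a mean of at least 10, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. No table holds both the triple mutant and the hrde-1 strain, and the tables were scaled separately. For this comparison the recovered reads of the 6 libraries were scaled together with edgeR's trimmed mean of M values (TMM), expressed as RPM and fitted with the same limma model over 3 groups. That design was chosen after seeing the data, and the plan had left this comparison untested for separately scaled tables. Levels set side by side for all 3 strains are from this joint scaling. Lists with at least 3 measured loci were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. Adjusted p-values of list tests are those at the preset correlation unless stated. Overlaps between the authors' tables were tested with Fisher's exact test, two-sided, over loci with an adjusted p in both tables, and adjusted over all overlaps. For tables that share libraries, overlaps were also counted in simulated unchanged groups, between lists of the smallest p in each direction as long as the authors' call lists; this count was chosen after the overlaps were seen. The p-values of single loci measure the spread between these samples, of which there are 2 per group, and that spread may be technical. Camera at the preset correlation assumes how far the loci of a list vary together. The p-values of Fisher's exact test and of the permutation test of neighbouring loci count loci as independent units and hold no spread between samples.

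The named genes of a comparison are hrde-1, meg-3 and meg-4, rde-11 and sid-1 from the series title, the 10 largest rises and 10 largest falls among called loci with a mean of at least 50 and groups that do not overlap, and up to 4 members of each list with the smallest adjusted p. For the authors' tables the mean is in RPM over the 6 libraries, without N2, and overlap of groups was not considered. Other loci are named as chosen after their values were seen.

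Alternatives covered the pseudocount (0.5 and 5), the filter on low values, scaling to library totals, to miRNA reads and by median of ratios, the libraries in the fit, the tool (edgeR quasi-likelihood and DESeq2 on recovered reads), the replicate number as a term, each replicate left out in turn and, for the authors' tables, an adjusted p under 0.01, a 2-fold change and a mean of at least 50 RPM. Where leaving out a replicate left 1 library in a group, limma assumes that it varies like the others.

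The limma comparisons were tested on simulated data with the dispersion of these libraries and 200 changed loci. Each locus was drawn independently, with the same dispersion in every strain and in a single draw per setting. In the data the SD of the difference between replicates was 0.45 in the triple mutant, 0.54 in hrde-1 and 0.68 in meg-3 meg-4. Loci of a group can also shift together in a library, so the simulated shares of false calls may not hold for these data. With the design for the triple mutant against meg-3 meg-4, 10.4% of 2-fold, 76.1% of 4-fold and 87.9% of 8-fold changes were called, 3.33% of calls were false, and 2 loci were called with no change simulated. With the design for the triple mutant against hrde-1, the shares were 11.9%, 88.1% and 95.5%, with 3.70% false calls, and 1 locus was called with no change simulated. Most 2-fold changes were thus not called at 2 libraries per group. Tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.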

Results

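Small RNAs were sequenced from whole young mothers of 3 C. elegans strains, with 2 libraries per strain. HRDE-1 is a germ line Argonaute that acts with small RNAs in the nucleus, and MEG-3 and MEG-4 are scaffold proteins of P granules, the RNA-protein condensates of the germ line. The strains were hrde-1, meg-3 meg-4, and the triple mutant hrde-1; meg-3 meg-4. The reads counted at annotated loci numbered 5450690 and 4604636 in the hrde-1 libraries, 6780320 and 2384147 in the triple mutant, and 5628602 and 5115457 in meg-3 meg-4.

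The mutated genes were looked at first. At meg-3 (listed as gei-12, F52D2.4, WBGene00001569) the hrde-1 libraries held 52 and 22 reads, the triple mutant 0 and 0, and meg-3 meg-4 2 and 3. At meg-4 (C36C9.1, WBGene00016485) the hrde-1 libraries held 48 and 39 reads, and all 4 libraries labelled as lacking meg-4 held 0, which allows up to 3 reads per library. At hrde-1 (C16C10.3, WBGene00007624) small RNA reads were present in every strain, with 4138 and 2218 in hrde-1, 1944 and 633 in the triple mutant, and 3640 and 3096 in meg-3 meg-4. The labels do not say which part of hrde-1 the tm1200 allele removes, so reads at this locus do not check the label.

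The series title names rde-11 and sid-1 as genes whose small RNAs are raised in meg-3 meg-4 mutants, and the comparison of the triple mutant with meg-3 meg-4 asks whether loss of hrde-1 lowers them. RDE-11 is needed for the amplification of small RNAs in RNA interference, and SID-1 is a channel that takes up double-stranded RNA. Small RNAs at rde-11 (B0564.11, WBGene00023421) fell in the triple mutant, from a deposited signal of 2755 ± 610.2 (SD, n = 2) in meg-3 meg-4 to 659 ± 46.6 (SD, n = 2), a log2 fold change of −2.05 (SE 0.30, limma adjusted p = 2.7e-04). Small RNAs at sid-1 (C04F5.1, WBGene00004795) fell from 2033 ± 789.1 to 610.4 ± 43.5 (SD, n = 2 each), a log2 fold change of −1.68 (SE 0.33, limma adjusted p = 0.00328). At both genes both triple mutant libraries lay below both meg-3 meg-4 libraries. Across 18 settings, the planned one included, the log2 fold change at rde-11 lay between −2.27 and −1.82, with an adjusted p of at most 0.00242, and that at sid-1 between −2.09 and −1.27, with an adjusted p of at most 0.0468. The median log2 fold change of all loci tested was −0.11, and −0.29 when the libraries were scaled to their totals. Relative to that median, rde-11 stood at −1.93 and sid-1 at −1.56 in the deposited scaling, and at −1.94 and −1.57 with scaling to totals.

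With all 6 libraries scaled together, small RNAs at rde-11 came to 416.3 ± 85.1 RPM in hrde-1, 729.9 ± 50.3 in the triple mutant and 2915 ± 550.2 in meg-3 meg-4 (SD, n = 2 each). Small RNAs at sid-1 came to 400.7 ± 70.4, 676.2 ± 49.4 and 2144 ± 765.8 in the same order. The triple mutant was higher than hrde-1 in both of its libraries at both genes, but the difference did not pass the test, with a log2 fold change of 0.82 (SE 0.32, limma adjusted p = 0.155) at rde-11 and 0.76 (SE 0.34, limma adjusted p = 0.251) at sid-1. When the libraries were scaled to miRNA reads these values turned to −0.30 and −0.36, again without a call, while the median of all loci moved from −0.18 to −1.26. Relative to the median, rde-11 stood at 1.00 and sid-1 at 0.94, and at 0.96 and 0.90 with scaling to miRNA reads. In the authors' deposited table of hrde-1 over N2, the log2 fold change was −0.16 at rde-11 (adjusted p = 0.777) and −0.25 at sid-1 (adjusted p = 0.612). In the authors' deposited table of the triple mutant over N2 it was 0.59 at rde-11 (adjusted p = 0.00475) and 0.44 at sid-1 (adjusted p = 0.0542). The authors' deposited table of the triple mutant over N2 minus that over meg-3 meg-4 leaves 2.65 at rde-11 and 2.18 at sid-1 (log2) for meg-3 meg-4 over N2, a difference between separately scaled tables that has no test. Whether the effect of losing hrde-1 differs between the wild type and the meg-3 meg-4 background was not tested, since the N2 libraries were not used here.

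**Figure D1:**
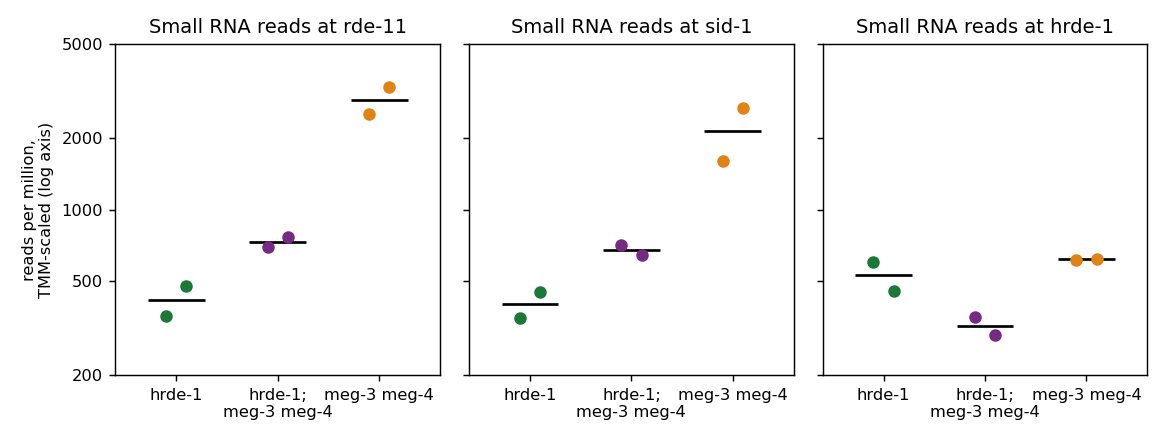
Small RNA RPM (TMM-scaled, log axis) at rde-11, sid-1 and hrde-1 in each library, with 2 points per strain and a line at their mean. At rde-11 the means were 416.3 in hrde-1, 729.9 in the triple mutant and 2915 in meg-3 meg-4.

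Beyond these genes, the triple mutant differed from meg-3 meg-4 at 470 of 6067 loci tested, with 261 higher and 209 lower. This excess of rises was not kept with library totals (167 higher, 188 lower), miRNA reads (198, 200) or TMM (226, 234). It was not kept either without triple mutant replicate 2 (101, 106) or without meg-3 meg-4 replicate 1 (311, 389). Protein-coding genes made up 209 of the higher and 178 of the lower loci, and 5130 of the 6067 tested. Of 74 loci with no match in the reference, 14 were higher and 5 lower. Among these were C46G7.3, Y48G1BM.4, ZK228.2 and T23B12.9, all higher, and Y55B1BR.5, which was lower. Among called loci with a mean of at least 50 and groups that do not overlap, the largest rises were at ZC15.1 (WBGene00013830), from 3.49 ± 1.65 to 200.6 ± 40.4, and at C46G7.3 (WBGene00016723), from 32.1 ± 12.4 to 1343 ± 233.2 (deposited signal, SD, n = 2 each). Further large rises were at the F-box gene fbxa-125, with a log2 fold change of 4.98 (SE 0.44, limma adjusted p = 2.5e-06), and at Y48G1BM.4 (4.86), C34C12.1 (4.77), ZK228.2 (4.62), T23B12.9 (4.34), the cuticlin-like gene cutl-14 (4.22), C03D6.1 (3.87) and the collagen gene col-111 (3.86). The call at col-111 ended without meg-3 meg-4 replicate 1 (adjusted p = 0.0745), without meg-3 meg-4 replicate 2 (adjusted p = 0.0531) and with scaling to totals (adjusted p = 0.0538). The level at col-111 in the triple mutant rested on replicate 1, with a deposited signal of 1280 in it and 120.8 in replicate 2, and that at cutl-14 was 45.79 and 202.95 in the same order. With the same limits, the largest falls were at Y53F4B.17 (WBGene00013163), from 968.6 ± 591.4 to 10.8 ± 8.76, and at lon-8 (WBGene00013352), a regulator of body length, from 145.0 ± 17.3 to 1.83 ± 0.18. B0564.2, which lies next to rde-11, fell from 2509.6 ± 583.8 to 74.2 ± 9.10. Falls were also large at Y55B1BR.5 (−5.54), Y55F3AM.14 (later named znf-782, −5.29), H25P19.1 (−4.78), Y53F4B.18 (−4.65), F41G4.7 (−4.51), C18H2.1 (later named lido-18, −4.51) and K09B11.4 (−4.30). Leaving out triple mutant replicate 1 gave 228 calls, triple mutant replicate 2 207, and meg-3 meg-4 replicate 2 880.

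**Figure D2:**
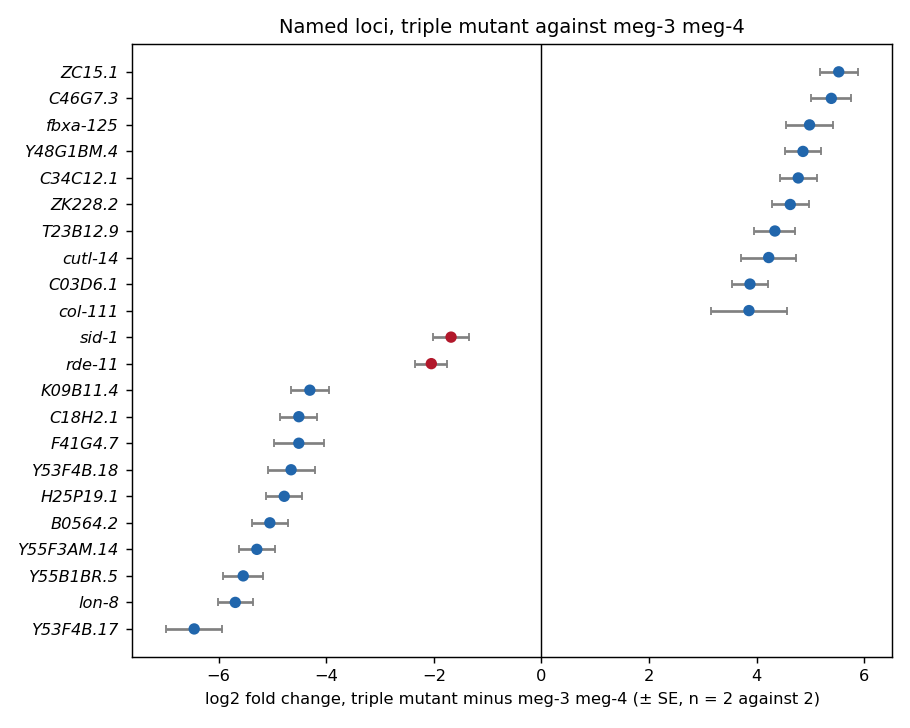
Log2 fold change of the triple mutant minus meg-3 meg-4 (points, limma; bars, SE; n = 2 against 2) at the 10 largest rises and 10 largest falls among called loci with a mean of at least 50 and groups that do not overlap, in blue, and at rde-11 (−2.05) and sid-1 (−1.68), in red. The values run from −6.45 at Y53F4B.17 to 5.52 at ZC15.1.

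Among genes of the RNA interference and small RNA list, 3 of 56 measured changed between the triple mutant and meg-3 meg-4, and the count adjusted over the list alone was also 3. These were rde-11, sid-1 and the helicase gene eri-6, which rose (log2 fold change 1.46, SE 0.23). Over all loci tested, 470 of 6067 were called. The list member rrf-2 was lower in the authors' deposited table of this comparison (−1.27, adjusted p = 0.0168) and just missed the threshold with limma (−1.23, limma adjusted p = 0.0521). The Argonautes (11 measured), P granule genes (22), oocyte genes (19), germ line and meiotic genes (19), histone genes (15), ERGO-1 targets (5) and a list chosen by name that held 6 snRNAs and 3 protein-coding genes (9) had 0 calls with limma, over all loci and adjusted over the list alone. At an unadjusted p under 0.05, limma gave 1 Argonaute, 2 histone genes and 1 snRNA locus of these, edgeR called 0 and DESeq2 called 1 histone gene, his-67. Without meg-3 meg-4 replicate 2 the P granule, germ line, Argonaute, oocyte and RNA interference lists passed the camera test at the preset correlation, each with more lower than higher members. At an estimated correlation 0 of the 139 list tests in the alternatives passed. In that fit 2 histone genes were higher. By annotation class, 1 of 78 snoRNA loci was higher (W03B1.17, 1.31), and of 19 snRNA loci F56A12.5 was higher (1.57) and M163.13 lower (−2.72). These calls came to 0 with scaling to totals. Without either triple mutant library 1 snRNA was lower and 0 snoRNAs were called. When meg-3 meg-4 replicate 1 was left out, 1 snoRNA was higher and 4 lower, and 1 snRNA higher and 2 lower. When replicate 2 was left out, 6 snoRNAs and 3 snRNAs were higher. Without meg-3 meg-4 replicate 1, 2 ERGO-1 targets and 1 Argonaute were lower, 1 histone gene and 1 P granule gene higher, and the RNA interference list had 2 higher and 4 lower. Of the 26 nuclear silencing factors, lin-15B fell (−1.47, SE 0.43), a call that was not made when adjusted over the list alone or without either triple mutant library. With meg-3 meg-4 replicate 2 left out, 1 of these factors was higher and 4 were lower. Of 7 HRDE-1 targets listed from memory, F15D4.5 (−2.89) and C38D9.2 (−2.91) fell and eri-6 and bath-20 (1.07) rose, and all 4 were called adjusted over the list alone. Without either triple mutant library 1 rise was left. eri-6 stands in both this list and the RNA interference list. Of 55 F-box genes 6 were higher and 10 lower (8 and 12 adjusted over the list alone), with fbxa-60 (3.38), fbxa-10 (2.86) and fbxa-115 (−3.03) among them. F-box calls moved to 5 higher and 3 lower without triple mutant replicate 1, to 6 and 3 without triple mutant replicate 2, and to 13 and 11 without meg-3 meg-4 replicate 2.

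Small RNAs at the BATH and MATH domain genes were higher at 4 and lower at 1 of 31 (5 and 4 adjusted over the list alone), with math-49 (3.01), math-44 (2.08) and bath-2 (−1.59) called. Without triple mutant replicate 1 the list had 1 call, and without meg-3 meg-4 replicate 1 there were 4 higher and 5 lower. Among 21 seven-transmembrane receptor genes, srh-171 fell (−3.88) and sru-17 rose (3.46), and both were called adjusted over the list alone. Leaving out meg-3 meg-4 replicate 2 gave 5 higher receptor genes, and leaving out either triple mutant replicate gave 0 higher. Of 5 spermatogenesis genes, spe-41 fell (−1.24, SE 0.35), also adjusted over the list alone, and this call ended without either triple mutant library, without meg-3 meg-4 replicate 2 and with either other scaling. Median, mean and camera direction differed in sign for the BATH and MATH list (−0.12, 0.14, up), the receptor list (−0.08, −0.04, up) and the spermatogenesis list (0.16, −0.03, up), and none of these passed the camera test. Neuronal genes (2 measured, nlp-12 higher by 2.13), major sperm protein genes (1, msp-50, 0.60 with no call) and ribosomal RNA (1, rrn-2.1, −0.06 with no call) were too few for a list test.

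In 6 lists the triple mutant and meg-3 meg-4 differed by camera at the preset correlation, and in none with an estimated correlation (adjusted p = 0.977 with an estimated correlation for each list). In the alternatives 0 of 139 list tests passed at an estimated correlation (lowest adjusted p = 0.655 with camera). The correlation was estimated from 2 libraries per group and came to 0.41 for the 21U loci. Loss of a call at this setting therefore does not show that a list was unchanged. The 6 vitellogenin genes, which encode yolk proteins, had 5 lower members (6 adjusted over the list alone, camera adjusted p = 3.1e-05), with vit-6 at −3.40 (SE 0.79), vit-2 at −3.17 and vit-5 at −3.05. The size of this fall rested on meg-3 meg-4 replicate 2: vitellogenin loci took 288.3 and 3145 RPM in the meg-3 meg-4 libraries against 123.2 and 71.3 in the triple mutant, and the authors' deposited table called 0 of them, edgeR 5. Without meg-3 meg-4 replicate 2 the list had 3 lower members (camera adjusted p = 0.0390), and scaling to totals gave 0 calls. Ribosomal protein genes had 5 lower members of 61 (20 adjusted over the list alone, camera adjusted p = 2.1e-10), with rpl-38 at −1.72, rpl-4 at −1.33 and rpl-3 at −1.28, but 0 calls without either triple mutant library and 18 lower without meg-3 meg-4 replicate 1. Of 416 loci of 21U-RNAs, the piRNAs of C. elegans, 18 were higher and 1 lower (0 adjusted over the list alone, camera adjusted p = 9.1e-13), with 21ur-3065 at 1.39 and 21ur-1242 at 1.62. The 21U calls were 0 without either triple mutant library, 28 higher and 5 lower without meg-3 meg-4 replicate 1, 54 higher without meg-3 meg-4 replicate 2, and 0 higher with scaling to totals or to miRNA reads. Collagen genes had 3 higher members of 9 (5 adjusted over the list alone, camera adjusted p = 0.0337), namely col-38 (2.42), col-111 and col-121 (3.14). Only these 9 of 175 collagen loci passed the filter on the mean. Over 32 collagen loci in the authors' deposited table of this comparison the direction was the opposite. Their median was −1.76 against −0.32 to 0.19 in random lists, with 2 called higher and 0 lower. The collagen list lost its call without triple mutant replicate 1 (0.104) and without meg-3 meg-4 replicate 1 (0.676, with 1 higher and 2 lower), and had 1 higher with scaling to totals. The 118 miRNAs had 2 higher members, mir-8191 (3.06) and mir-2209.1 (1.81), and 1 lower, mir-2214 (−2.87), the same count adjusted over the list alone, with a camera adjusted p of 0.0337 that ended without triple mutant replicate 1 (0.763), without meg-3 meg-4 replicate 1 (0.946) and with scaling to totals (0.292) or miRNA reads (0.161). Without meg-3 meg-4 replicate 2, 8 were higher. The 3 measured muscle genes had 0 calls over all loci with limma and 3 lower adjusted over the list alone and at an unadjusted p under 0.05 (unc-22 −2.45, unc-54 −1.98, act-2 −0.85; camera adjusted p = 0.0337, or 0.148 with scaling to totals and 0.0525 with scaling to miRNA reads). Of these 3, edgeR and DESeq2 called unc-22 alone. The falls at unc-22 and unc-54 rested in size on meg-3 meg-4 replicate 2, and muscle loci took 72.8 and 257.65 RPM in the meg-3 meg-4 libraries against 31.9 and 29.4 in the triple mutant. Without that library act-2 alone was measured (−1.22, adjusted p = 0.0450), too few for a list test. Of 4 muscle genes measured without meg-3 meg-4 replicate 1, unc-22, unc-54 and unc-89 were called lower, and without either triple mutant library 1 gene of 5 was.

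The authors' deposited tables set strains that lack hrde-1 against strains that carry it, in the wild type and in the meg-3 meg-4 background. The tables of hrde-1 over N2 and of the triple mutant over meg-3 meg-4 share no library. In the authors' deposited table of the triple mutant over meg-3 meg-4, 281 loci were called higher and 223 lower among 11674 with an adjusted p in both tables. Of these, 218 were also higher in hrde-1 over N2, against 27.4 by chance (Fisher's exact test, odds ratio 39.4, 95% interval 29.4 to 53.5, adjusted p = 4.1e-168). Likewise 147 were lower in both, against 16.7 by chance (odds ratio 28.5, 95% interval 21.3 to 38.5, Fisher's exact test, adjusted p = 1.7e-112). Opposite calls numbered 10 (21.7 by chance) and 6 (21.01 by chance). These chance values take every locus as equally likely to be called, but calls were more frequent at loci with a high mean over the 6 libraries. That mean leaves out N2 and comes mostly from libraries that lack hrde-1. Loci higher without hrde-1 therefore pass a filter on it more readily, so it does not measure abundance alone. Of 2188 loci with a mean of at least 50 RPM, 571 were higher in hrde-1 over N2 and 186 in the triple mutant over meg-3 meg-4, with 154 higher in both. Lower calls there numbered 174 and 113, with 69 lower in both, and no chance value was made for these loci. Genes called in the same direction in the authors' deposited tables of both backgrounds included fbxa-125 (3.70 in hrde-1 over N2 and 4.86 in the triple mutant over meg-3 meg-4), lon-8 (−5.83 and −6.28), C18H2.1 (−4.90 and −4.56), srh-171 (−6.78 and −4.37) and F15D4.5 (−3.38 and −2.90). rde-11 and sid-1 were not among them. Of the 209 loci lower in the triple mutant by limma, 131 were lower in the authors' deposited table of hrde-1 over N2 and 66 had no call there.

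**Figure D3:**
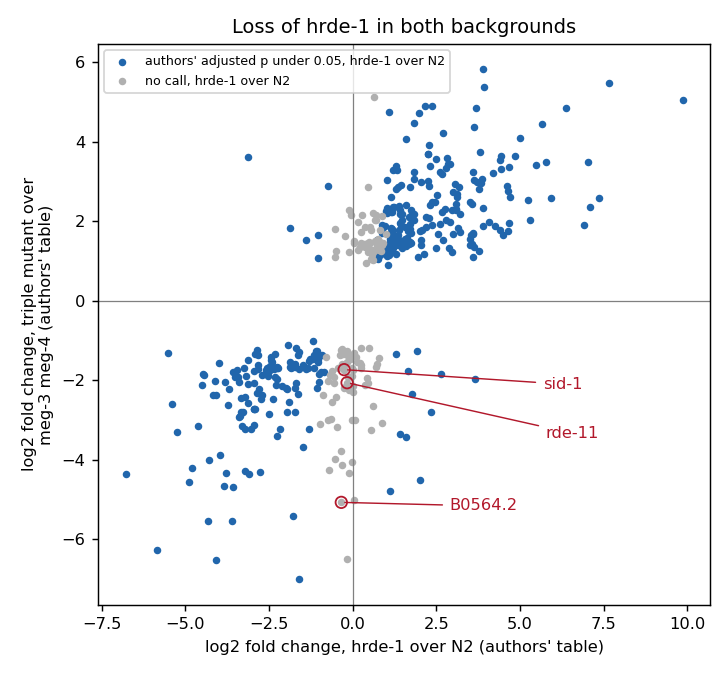
Log2 fold changes in the authors' deposited tables at 469 loci called by limma between the triple mutant and meg-3 meg-4, with hrde-1 over N2 on the x axis and the triple mutant over meg-3 meg-4 on the y axis. Blue points, 348 loci, were called in hrde-1 over N2 and grey points were not; red circles mark rde-11, sid-1 and B0564.2, which lie near 0 on the x axis.

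Among those 209 lower loci, 37 (33 of them protein-coding) resembled rde-11 and sid-1 in having no call in hrde-1 over N2 and not being lower in the triple mutant over N2, a group defined after the values were seen. B0564.2 came to 38.8 RPM in hrde-1, 82.2 in the triple mutant and 2654 in meg-3 meg-4 (jointly scaled means, n = 2 each). The homeodomain gene ceh-20 came to 273.7, 247.0 and 1118, madf-5 to 215.7, 267.5 and 1129, qdpr-1 to 303.7, 561.7 and 1817, and B0250.7 to 376.3, 518.5 and 1616 in the same order. The yolk protein genes vit-1, vit-2, vit-3, vit-5 and vit-6 were in this group as well, with the dependence on meg-3 meg-4 replicate 2 given above.

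The triple mutant was set against hrde-1 to ask what loss of meg-3 and meg-4 changes where hrde-1 is already lost. Of 6469 loci tested, 665 were called, with 283 higher and 382 lower, and 140 of the lower loci but 11 of the higher ones had changed at least 8-fold. Among called loci with a mean of at least 50 RPM and groups that do not overlap, the largest rise was at mltn-3 (W02B8.3, WBGene00012199), from 2.89 ± 0.0200 RPM in hrde-1 to 1186 ± 11.3 in the triple mutant (SD, n = 2 each), with 938.5 in meg-3 meg-4. The thiamine pyrophosphokinase gene tpk-1 (ZK637.9, WBGene00014027) rose from 224.0 ± 38.4 to 3353 ± 531.6 (SD, n = 2 each). Other large rises were at fbxa-60 (log2 fold change 4.44), Y54F10BM.13 (3.75), fbxa-10 (3.71), pqn-24 (3.69), the aldolase gene aldo-1 (3.397), dhs-9 (3.19), C30F12.5 (3.07) and R186.1 (later named hrg-9, 2.52). The call at dhs-9 ended in each fit without 1 hrde-1 library, without triple mutant replicate 1, with either other scaling and with DESeq2, and that at pqn-24, with 6.87 and 73.1 RPM in the triple mutant libraries, without hrde-1 replicate 1 and with scaling to totals. Small RNAs at Y20F4.9 (WBGene00206476) fell from 852.4 ± 246.6 to 12.7 ± 0.71, and at T20F5.5 (WBGene00020627) from 245.4 ± 92.2 to 3.52 ± 1.67 (SD, n = 2 each). With the same limits, large falls were also seen at tctn-1, which encodes a protein of the ciliary transition zone (−5.67), the peroxisome gene prx-11 (−5.60), D2045.5 (−5.58), Y53F4B.17 (−5.51), F36A2.3 (−5.45), ZK673.4 (−5.43), the spermidine synthase gene spds-1 (−5.43) and Y48B6A.17 (−5.17).

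The balance of these calls between the triple mutant and hrde-1 depended on single libraries and on the scaling, which moved the median of all loci from −0.18 to −0.60 with library totals and to −1.26 with miRNA reads. There were 98 higher and 483 lower with library totals, and 41 higher and 5043 lower with miRNA reads. Without hrde-1 replicate 1 there were 367 calls (64 higher, 303 lower) and without triple mutant replicate 1 there were 416 (86 higher, 330 lower). Without triple mutant replicate 2 there were 542 (201 higher, 341 lower). The balance turned without hrde-1 replicate 2 (256 higher, 219 lower) and with edgeR on 4 libraries (637 higher, 617 lower). Of the 382 lower loci, 261 were higher in the authors' deposited table of hrde-1 over N2, and of the 140 lower by at least 8-fold 111 were. Both comparisons hold the hrde-1 libraries, so part of these counts may come from chance values in them.

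miRNAs had the smallest camera p of the lists compared between the triple mutant and hrde-1. Of 116 measured, 55 were higher and 0 lower (92 and 0 adjusted over the list alone; camera adjusted p = 4.5e-36, adjusted p = 0.621 with an estimated correlation), and their median log2 fold change was 1.08, or 1.25 relative to the median of all loci. mir-82 rose from 21819 ± 2656 to 58965 ± 15141 RPM (SD, n = 2 each), and mir-249 (2.15), mir-246 (1.75) and mir-90 (1.35) rose as well. The count fell to 11 without hrde-1 replicate 1, 14 without triple mutant replicate 1 and 16 without triple mutant replicate 2, to 15 with scaling to totals, and to 4 higher and 9 lower with scaling to miRNA reads. As a share of a library's reads, miRNA loci took 18.9% ± 0.93 in hrde-1, 30.4% ± 2.47 in the triple mutant and 31.4% ± 0.30 in meg-3 meg-4 (SD, n = 2 each). Protein-coding loci took 63.9% ± 2.75, 51.4% ± 3.08 and 50.8% ± 1.21, and 21U loci 3.88% ± 0.46, 3.19% ± 0.19 and 2.73% ± 0.22.

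**Figure D4:**
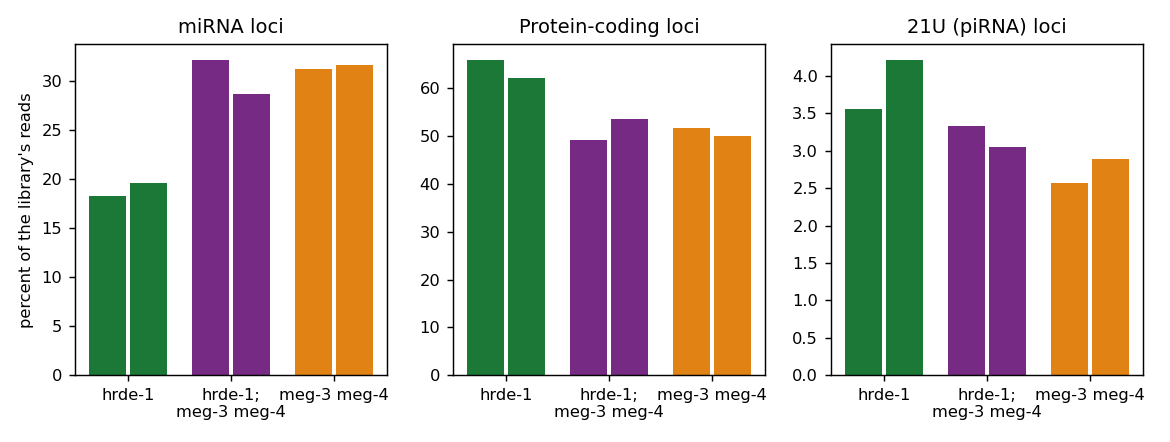
Percent of each library's reads at miRNA, protein-coding and 21U loci, 1 bar per library and 2 libraries per strain. miRNA loci took 18.9% on average in hrde-1, 30.4% in the triple mutant and 31.4% in meg-3 meg-4.

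Other lists that differed between the triple mutant and hrde-1 by camera at the preset correlation each lost the call with an estimated correlation. All 3 measured neuronal genes, egl-21 (−3.42), ida-1 (−2.59) and nlp-12 (−1.71), which act in neuropeptide signalling, were lower, also adjusted over the list alone (camera adjusted p = 4.7e-04, adjusted p = 0.621 with an estimated correlation). Of 5 ERGO-1 targets, of which 1 is annotated as a miRNA, K02E2.6 (1.60) and C44B11.6 (1.40) rose, with 3 higher adjusted over the list alone (camera adjusted p = 0.00108, adjusted p = 0.621 with an estimated correlation), and both single calls ended without hrde-1 replicate 1 and without triple mutant replicate 1. Of 7 HRDE-1 targets listed from memory, eri-6 (1.71), bath-20 (1.58) and Y37E11B.2 (1.47) rose, also adjusted over the list alone (camera adjusted p = 0.00661, adjusted p = 0.621 with an estimated correlation), and with scaling to miRNA reads 2 were higher and 4 lower. eri-6 was higher in the triple mutant than in either other strain, at 9399 ± 552.7 RPM against 2902 ± 594.6 in hrde-1 (SD, n = 2 each). Of 14 histone genes, his-3 (1.58) and his-62 (1.31) rose, also adjusted over the list alone (camera adjusted p = 0.00856, adjusted p = 0.621 with an estimated correlation), but the list lost its call without triple mutant replicate 1 (0.0712). Both single calls ended without that library or hrde-1 replicate 1, and 1 was left without hrde-1 replicate 2. In this list 5 were lower with scaling to miRNA reads. The 444 loci of 21U-RNAs had 21ur-13215 (1.27) higher and 21ur-4880 (−1.39) lower, and 0 adjusted over the list alone (camera adjusted p = 6.5e-04, adjusted p = 0.850 with an estimated correlation). The 21U call ended without hrde-1 replicate 1 (0.970) and without triple mutant replicate 1 (0.126), as well as with scaling to totals (0.0551) or to miRNA reads (0.771, with 318 lower).

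The remaining lists did not pass the camera test between the triple mutant and hrde-1. Passes of these lists in single alternatives, given below, are at the preset correlation, and at an estimated correlation 0 of 140 list tests in the alternatives passed (lowest adjusted p = 0.148). Collagen genes had 4 lower of 9 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0561), with col-121 at −4.45, col-103 at −2.36 and col-38 at −2.18. The collagen list passed without triple mutant replicate 1 (1.3e-04) and without hrde-1 replicate 1 (0.0115), and had 2 lower without hrde-1 replicate 2. Receptor genes had 4 lower of 22 (4 adjusted over the list alone), namely srg-65 (−3.09), srg-66 (−2.50), srsx-25 (−2.37) and sru-17 (−2.23). F-box genes had 4 higher and 2 lower of 58, the same adjusted over the list alone, and the list passed without hrde-1 replicate 2 (0.00694, with 6 higher and 1 lower). BATH and MATH genes had 4 higher and 4 lower of 36 (6 and 5 adjusted over the list alone), with math-30 (−3.57), math-22 (−3.47) and bath-28 (−2.38) lower. The list passed without hrde-1 replicate 2 (0.0469, with 4 higher and 1 lower), while 1 was higher without any single one of the other 3 libraries. Of 58 RNA interference genes eri-6 alone was called, also adjusted over the list alone, and the list chosen by name with 6 snRNAs and 4 protein-coding genes had 1 call, the protein-coding gene ncs-6 (−2.06), also adjusted over the list alone. By annotation class 7 of 79 snoRNA loci were higher and 1 of 18 snRNA loci was lower (F56A12.5, −1.36). The snoRNA count fell to 0 without hrde-1 replicate 1 and to 1 without triple mutant replicate 1, became 1 higher and 1 lower with scaling to totals, and was 18 lower with scaling to miRNA reads. The snRNA call was kept without hrde-1 replicate 1 and ended without any single one of the other 3 libraries. The Argonautes (11), P granule genes (22), oocyte genes (20), germ line and meiotic genes (20), nuclear silencing factors (26), ribosomal protein genes (61), spermatogenesis genes (5) and vitellogenins (6) had 0 calls with limma, over all loci and adjusted over the list alone. Of their 171 measured entries, 9 passed an unadjusted p under 0.05, edgeR called 6, among them 4 vitellogenin genes, and DESeq2 called 2, vit-2 and hda-3. Without hrde-1 replicate 2, the P granule (0.00786), oocyte (0.00816) and germ line (0.00897) lists passed the camera test at the preset correlation. The vitellogenins passed without triple mutant replicate 2 (7.3e-04, with 3 higher) and with scaling to totals (0.00880) or miRNA reads (1.5e-05). P granule loci took 7245 and 3976 RPM in the hrde-1 libraries, 2819 and 3119 in the triple mutant and 5064 and 2646 in meg-3 meg-4. Of 2 muscle genes measured act-2 fell (−1.39), and the single major sperm protein gene (msp-50, 0.09) and ribosomal RNA locus (rrn-2.1, 0.40) had no call. Median, mean and camera direction differed in sign for the list with ncs-6 (0.26, −0.07, up), the F-box list (−0.0013, 0.14, up) and the BATH and MATH list (−0.05, −0.17, up).

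In the authors' deposited table of hrde-1 over N2, which sets the single mutant against the wild type, 1214 loci were higher and 998 lower of 13876. Other differences between these 2 strains cannot be told apart from loss of hrde-1 there. Among called loci with a mean of at least 50 RPM over the 6 libraries, which do not include N2, the largest rises in the authors' deposited table were at C42D4.19 (12.27), the collagen gene col-121 (9.86), Y61A9LA.7 (7.67), the hedgehog-related gene wrt-5 (7.45), unc-87 (7.37), C07G1.7 (7.10), the intraflagellar transport gene ift-20 (7.03), F55B11.1 (later named xdh-1, 6.93), tctn-1 (6.75) and the Smad gene sma-2 (6.75). With the same limit, the largest falls there were at lon-8 (−5.83), C18H2.1 (−4.90), ads-1 (−4.80), B0001.5 (−4.53), Y55B1BR.5 (−4.33), fbxa-61 (−3.999), F27C1.18 (−3.97), K09B11.4 (−3.79), T23B12.14 (−3.72) and F47B7.6 (−3.58). Small RNAs at meg-4 (C36C9.1) were lower in hrde-1 than in N2 in the authors' deposited table (−2.78, adjusted p = 3.3e-13). F-box genes had 5 higher and 41 lower of 160, with a median of −0.73 against −0.15 to 0.16 in random lists. Receptor genes had 6 higher and 17 lower of 108 (median −0.45, percentile 0.4 among random lists), and collagen genes 7 higher and 2 lower of 36 (median 0.59, percentile 99.99). HRDE-1 targets listed from memory had 3 lower of 7, F15D4.5 (−3.38), C38D9.2 (−3.40) and bath-20 (−1.02), and ERGO-1 targets 2 lower of 6. The neuronal genes egl-21 (3.49), ida-1 (2.23) and nlp-12 (1.40) were higher and unc-31 (−2.45) lower. miRNAs had 9 higher and 5 lower of 154, and 21U loci 60 higher and 11 lower of 2300.

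In the authors' deposited table of the triple mutant over N2, 1104 loci were higher and 1265 lower of 12595. With the same limit on the mean, the largest rises there were at mltn-3 (9.41), C42D4.19 (8.40), ift-20 (7.43), F41C3.8 (7.31), wrt-5 (7.03), pqn-24 (6.59), col-121 (6.39), ugt-22 (6.34), fbxa-125 (6.06) and Y54F10BM.13 (6.01). With that limit the largest falls were at lon-8 (−6.49), Y20F4.9 (−6.36), F47B7.6 (−6.25), Y53F4B.17 (−5.64), prx-11 (−5.64), Y55F3AM.14 (−5.25), Y55B1BR.5 (−5.07), Y41C4A.12 (−5.03), dct-10 (−4.90) and spds-1 (−4.74). miRNAs had 98 higher and 2 lower of 150, with a median of 1.07 against 0.13 to 0.40 in random lists. F-box genes had 9 higher and 39 lower of 142 (median −0.70), receptor genes 2 higher and 19 lower of 83 (median −0.65), and 21U loci 99 higher and 16 lower of 1848 (median 0.32). Among RNA interference genes, 9 were higher and 6 lower of 69, with eri-6 (1.68) and nrde-2 (1.21) higher and hrde-1 (−0.90) and rrf-2 (−0.89) lower. The calls of this table overlapped those of hrde-1 over N2 at 490 loci higher in both (99.5 by chance) and 726 lower in both (100.3 by chance), and those of the triple mutant over meg-3 meg-4 at 219 (26.9 by chance) and 175 (22.01 by chance). These pairs of tables share the N2 or the triple mutant libraries. Unchanged groups against shared libraries were simulated in 20 draws at 12583 loci, and lists of the smallest p, as long as the authors' call lists, were overlapped. The triple mutant libraries were the shared ones in every draw and stood in for N2, whose depth and spread were not used. At a DESeq2 adjusted p under 0.05 these draws gave at most 1 call in a comparison and an overlap of 0. For the tables that share N2 the lists of the smallest p overlapped at 395.35 higher and 351.1 lower loci on average (417 and 366 at most). For the tables that share the triple mutant they overlapped at 143.75 and 101.6 (153 and 121 at most). These simulated lists hold chance values alone, so part of the excess over independent lists may come from the shared libraries.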

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

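The comparison of the triple mutant with hrde-1 as a whole, TMM scaling and the 6-library fit for the triple mutant against meg-3 meg-4, both edgeR fits, the crossed replicate numbers, the counts of snRNA and snoRNA loci by class, and list tests at an estimated correlation within the alternatives were chosen only after the data were seen. For the triple mutant against meg-3 meg-4 the count of 470 stayed within 1.5 times under every alternative run (355 to 700 calls) apart from leave-one-out, where it ranged from 207 to 880, lowest without triple mutant replicate 2 and highest without meg-3 meg-4 replicate 2. For the triple mutant against hrde-1 the count of 665 became 5084 with scaling to miRNA reads, since most loci then lay below the miRNAs, and 1254 with edgeR's quasi-likelihood test on 4 libraries, which tested 11634 loci; leave-one-out fits ranged from 367 to 542. The log2 fold changes at rde-11 and sid-1 in that comparison reversed to −0.30 and −0.36 with scaling to miRNA reads, which lowers every locus alike. With the replicate block, the triple mutant against meg-3 meg-4 gave 438 calls, 411 of them shared with the fit without it, and the triple mutant against hrde-1 gave 831. Replicates with the same number did not deviate together in the pairs of strains compared here (correlations of −0.11 between the triple mutant and meg-3 meg-4 and −0.19 between the triple mutant and hrde-1), though they did between meg-3 meg-4 and hrde-1 (0.56), so the numbers are not taken to pair the triple mutant with either strain. Crossing the numbers in the triple mutant gave 659 and 894 calls. Among the list tests, the replicate block changed 3 calls: miRNAs in the triple mutant against meg-3 meg-4 lost it (adjusted p = 0.208), and in the triple mutant against hrde-1 collagens (0.0379) and vitellogenins (0.0374) gained it, and it changed no other list call. With loci of a mean of at least 50 RPM only, which tests fewer loci, the authors' calls came to 745 for hrde-1 over N2, 986 for the triple mutant over N2 and 299 for the triple mutant over meg-3 meg-4. Under the same filter, loci lower in both hrde-1 over N2 and the triple mutant over meg-3 meg-4 came to 69, loci higher or lower in both hrde-1 over N2 and the triple mutant over N2 to 311 and 122, and loci lower in both tables of the triple mutant to 90. Of the other values, 763 for single loci and 303 for lists kept their direction and side of the threshold, 11 and 38 lost the call, and 6 and 18 gained it. The lost list calls include every list that passed at the preset correlation, with an estimated correlation and with fry. At hrde-1 itself the log2 fold change against meg-3 meg-4 was −0.996 (adjusted p = 0.0856) and passed with scaling to totals (0.0254) or miRNA reads (0.0322) and without either meg-3 meg-4 library (0.0244 and 0.0344), and against hrde-1 it was −0.69 (0.279) and passed with totals (0.0357) or miRNA reads (0.00292). For changes given here with no cause, the cause was not tested. At this depth and with 2 libraries per strain, 10.45% and 11.9% of simulated 2-fold changes were called in the designs of these comparisons, so smaller changes were mostly not detectable.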

Other observations

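The tests of neighbouring loci were chosen before their result was seen, and those on miRNA share and on yolk protein loci, like the groups of loci below, were chosen only after the values were seen. Strains were sorted at each locus by whether they came within 16-fold of the strain with the highest jointly scaled mean, among loci where that mean was at least 50 RPM. At 2543 loci all 3 strains did. Only hrde-1 and the triple mutant did at 76 loci, such as C46G7.3 (1834, 1488 and 33.8 RPM in hrde-1, the triple mutant and meg-3 meg-4) and col-111 (1125, 776.9 and 28.03). Another of these, frm-1 (2046, 146.3 and 106.4), lies near the limit, with similar means in the triple mutant and meg-3 meg-4 on either side of it. At col-111 the mean of the triple mutant rests on 1 library (1420 and 133.6 RPM). hrde-1 alone did at 53 loci, such as W02B8.2 (2579, 95.7 and 94.7), the neuropeptide receptor gene pdfr-1 (1238, 70.5 and 31.1) and the BBSome gene bbs-5 (594.8, 21.7 and 2.97). Another 21 loci, such as Y53F4B.17 (501.8, 11.9 and 1018) and Y55F3AM.14 (132.7, 12.5 and 508.9), fell outside that range in the triple mutant alone. Only meg-3 meg-4 came within it at 10 loci, among them B0564.2 (38.8, 82.2 and 2654), H25P19.1 (88.7, 90.8 and 2415) and ads-1 (23.8, 70.6 and 1245), and both strains lacking meg-3 and meg-4 did at 8, among them mltn-3 (2.89, 1186 and 938.5). The single locus of the triple mutant alone, dhs-9, rests on 1 library (776.0 and 56.7 RPM). These groups are descriptions of means of 2 libraries, without a test.

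Called loci next to each other in the genome moved the same way more often than shuffled calls, as B0564.2 did with rde-11, F15D4.6 (−2.66) with F15D4.5, and tag-344 (1.90) with fbxa-125. In the triple mutant against meg-3 meg-4, 19 of 2474 neighbouring pairs of protein-coding loci were called in the same direction, against a mean of 7.10 when the calls were shuffled (permutation test of 10000 shuffles, one-sided, p = 3e-04). Reads shared between overlapping genes do not account for this as a whole, since 14 pairs that do not overlap in the reference annotation were called in the same direction, against a mean of 6.26 in shuffles (permutation p = 0.004). In the triple mutant against hrde-1 there were 25 such pairs against 14.5 (permutation p = 0.006), and 21 against 12.6 among those that do not overlap (permutation p = 0.02). Spreading of small RNAs over neighbouring genes is a hypothesis that no test here addresses, and copies of a gene family that lie side by side, such as srg-65 and srg-66, stay open as a source of some of these pairs. The shuffles did not match loci on read level, so neighbours with similar levels stay open as a source as well.

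The share of miRNA reads was higher in all 4 libraries lacking meg-3 and meg-4 than in both hrde-1 libraries. A weaker capture of RNAs with a 5' triphosphate alone would raise 21U reads, which carry a monophosphate, by the same factor. The ratio of miRNA to 21U reads was at least 9.39 in those 4 libraries against 5.12 and 4.64 in hrde-1, a gap of 4.27 where replicates differed by at most 1.18. Weaker capture as the only change would not give this ratio. A change in the 21U-RNAs themselves would also move the ratio, so it cannot decide whether capture contributed. A smaller share of germ line and embryo RNA stays open: mir-35 to mir-42, miRNAs of oocytes and embryos, came to at most 4.38% of other miRNA reads in the 4 libraries against 6.47% and 4.74% in hrde-1. That margin is narrow next to the spread within meg-3 meg-4 (1.70% and 4.38%), and P granule loci, with 5064 RPM in meg-3 meg-4 replicate 1 against 3976 in hrde-1 replicate 2, were not lower throughout. Loss of meg-3 and meg-4 itself stays open, as does any other difference between the strains, and in the authors' deposited tables miRNAs were higher at 98 of 150 loci in the triple mutant over N2 and at 9 of 154 in hrde-1 over N2.

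Yolk protein loci were 10.9 times higher in meg-3 meg-4 replicate 2 than in replicate 1, and muscle loci 3.54 times. General breakdown of RNA in that library would raise reads from structural RNAs as well, and these were 1.28 times higher together. In replicates 1 and 2, snRNA loci took 0.063% and 0.107% of reads, snoRNA loci 0.82% and 1.04%, and rRNA loci 0.153% and 0.181%. All 3 classes were thus higher in replicate 2. Breakdown need not raise structural and messenger RNAs by the same factor, so these values do not decide the question. Whether the mothers were older, with more embryos, stays open: mir-35 to mir-42 were 2.57 times higher relative to other miRNAs in replicate 2, but loci of oocyte genes (1399 RPM in replicate 1 and 775.5 in replicate 2), germ line genes (1561 and 934.4) and P granule genes (5064 and 2646) were all lower there. Among the hrde-1 libraries, replicate 1 had the higher level of these miRNAs (6.47%) and the lower level of yolk protein reads (48.98 RPM against 58.2), so the measures do not move together in every strain. A difference between the worms of the 2 cultures in another respect stays open and was not tested.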
